A study of Pyrococcus furiosus with 21 samples.

How the data were processed

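Unirradiated reference RNA and RNA from cultures given 2500 Gy were compared on spotted arrays of PCR products from *Pyrococcus furiosus*. Per the labels, irradiated RNA carried Cy5 and reference RNA Cy3, with no dye swap labelled, each product was spotted at 2 places, and cultures were independent. The only values used were the deposited log ratios of the value table, 9216 spots by 21 columns. How the authors made them (background, normalisation, filters) is not given in the sources used here, and neither are the base of the logarithm and the direction of the ratio. The deposited column medians lay close to 0. They were -0.0063 and -0.00067 for the reference arrays, 0.0063 for 0 min, -0.00051, -0.00023, 0.0040 and -0.0028 for 20 min, -0.0051, -0.00045, -0.0047 and -0.0077 for 40 min, 0.0022, 0.0053, 0.0042 and -9.60e-05 for 60 min, and -0.00016, -0.0024, 0.0032 and 0.00040 for 120 min. Medians this close to 0 point to centring before deposit, which no source used here states, and scanner values were not used here. Filters applied by the authors may decide which spots have a value, and a log ratio of unknown base fixes ranks and signs but not folds.

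The 3 columns of the 0 min group were identical and were used as 1 sample. The position of duplicate spots was found from the values: of 1527 layouts tried, the layout that pairs mirrored blocks with a row shift of 12 and reversed columns gave a correlation of 0.693 between spots, and the next best gave 0.155. The 2 spots were averaged, and each array was centred on its median over all products with a value, the largest such median being 0.028. That set includes products that were not tested. Probes needed a value on at least 2 arrays of each group (1 for 0 min), which left 2056 of 2883 products with any value. Control spots could not be told from the others by the table and stayed in. No per-sample column was left unused.

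Groups were taken from the sample titles. All 19 arrays entered 1 limma fit (version 3.58.1 in R 4.3.3) with a mean per group and a shared spread, and contrasts were tested with empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. The test over the irradiated times used sums of squares computed from the group means with limma's posterior variances. Figures, layout and per-array values used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The fit was tested on simulated data with 2056 probes. Planted differences of 0.4 were recovered for 83% of probes between 120 min and the reference, 96% between 120 and 40 min, and 37% between 120 and 0 min. Planted differences of 0.2 were recovered for 16%, 19% and 1%. The simulated noise was normal and independent between probes, with limma's own posterior variances, whereas neighbouring spots on the real arrays were correlated. The shares recovered therefore hold for such simulated data only.

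The comparisons with the reference and with 0 min, the test over the irradiated times and most alternatives were fixed before the data were examined. The 6 comparisons between the 20, 40, 60 and 120 min groups were added after the 0 min columns proved identical and after their counts had been seen, and the comparisons of spread, the removal of the slide-position trend and the fit without the 0 and 20 min arrays were also chosen after seeing the data. The position trend was a Gaussian-weighted mean of neighbouring spots within a block (SD 2 spots), leaving out the spot itself. The alternatives were values not centred, arrays scaled to an equal median absolute deviation (by median absolute values, since the planned function divides by array medians near 0), probes with a value on all arrays (1847), robust moderation, both spots kept with an estimated correlation, 2 groups fitted alone, the ratio against 0, a replicate block, and each array left out in turn.

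The planned tests of 23 gene lists, among them DNA repair, oxidative stress, heat shock and ribosomal proteins, were not run because the files do not pair probes with genes. The rule for named genes, fixed beforehand, took the 5 largest rises and 5 largest falls of each contrast, members of the lists and a few genes by name, and could not be applied without gene names. In its place 2 probes that rose and 2 that fell at 40 min are given, a choice of time made after the results were seen.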

Results

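*Pyrococcus furiosus*, a hyperthermophilic archaeon that grows near the boiling point of water, was exposed at 4 °C to 2500 Gy of gamma radiation delivered at 73 Gy per min and then returned to 90 °C. RNA sampled 0, 20, 40, 60 and 120 min after the cultures reached 90 °C was hybridised to 2-colour arrays of PCR products against RNA from unirradiated cells, and 2 further arrays carried the unirradiated RNA in both channels. The design text also names a later sample, which was not analysed here. The 20, 40, 60 and 120 min groups held 4 arrays each. The 3 columns of the 0 min group held identical values and were counted as 1 sample, which left 19 distinct arrays of the 21 deposited columns. Between 3556 and 5411 of the 9216 spots of an array had a value, and the number of arrays limits the precision of every comparison. Positive log ratios are likely to mean more RNA in irradiated cells, because the labels place irradiated RNA in the Cy5 channel, but the table states neither the direction nor the base of the logarithm. Higher and lower therefore refer to the deposited log ratio. The files do not pair the probes with genes, so the results are given for probes, each the mean of 2 spots recovered as duplicates from the values.

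More probes differed from unirradiated cells at 20, 40 and 60 min than at 120 min. Against the reference arrays (n = 2), 198 of 2056 probes were higher and 160 lower at 20 min (n = 4), 113 were higher and 84 lower at 40 min (n = 4), and 82 were higher and 37 lower at 60 min (n = 4). At 120 min (n = 4) 6 probes were higher and 1 was lower, with 232 probes at an unadjusted p under 0.05. That low count depends on the reference arrays, which also remove any dye bias of single probes, since no dye swap is labelled. With the ratio tested against 0 in their place, such bias stays in, and 217 probes were higher and 117 lower at 120 min. At 0, 20, 40 and 60 min 174, 795, 682 and 666 were then called. The single 0 min sample had 37 higher and 25 lower probes. The median size of the called differences was 0.35 log units at 20 min, 0.37 at 40 min and 0.39 at 60 min, with a median standard error of 0.093 at each time. At 120 min it was 0.51. The smallest difference called was 0.20, 0.23, 0.25 and 0.40 at 20, 40, 60 and 120 min, so these medians do not show larger changes with time. A size of 0.37 is a 1.29-fold difference if the logarithm has base 2 and 2.34-fold if it has base 10. Calls are limma tests at a Benjamini-Hochberg adjusted p under 0.05. The reference cells were neither chilled nor rewarmed, so these contrasts hold chilling, irradiation and rewarming together. The 0 and 20 min arrays also differed from the reference arrays in which spots held a value (871 seldom-measured spots with a value at 0 min and 643 to 1098 at 20 min, against 1 and 4 on the reference arrays). Whether the count itself falls with time was not tested, and with the slide-position trend removed it was 301 at 20 min, 174 at 40 min, 179 at 60 min and 12 at 120 min. Without reference replicate 1 the counts were 136 at 20 min, 93 at 40 min, 53 at 60 min and 28 at 120 min, where the balance turned to 10 higher and 18 lower. Without reference replicate 2 they were 14 at 0 min, 131 at 20 min, 51 at 40 min (42 higher and 9 lower), 31 at 60 min (31 higher and 0 lower) and 1 at 120 min. Among the irradiated arrays, the 20 min count was 238 without replicate 2, and the 60 min count was 70 without replicate 1 and 72 without replicate 3. The 120 min count was 1, 2 and 4 without replicates 2, 3 and 4. With the arrays scaled to an equal spread, 111 probes were higher and 85 lower at 60 min, and 50 were higher and 40 lower at 120 min. With the values as deposited, without centring, the 0 min sample had 51 higher and 21 lower probes. Lower calls outnumbered higher ones for the 0 min sample when both spots were kept and when only the 2 groups were fitted. The reference arrays tested against 0 gave 0 calls in limma, with 217 of 2056 probes at an unadjusted p under 0.05.

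**Figure D1:**
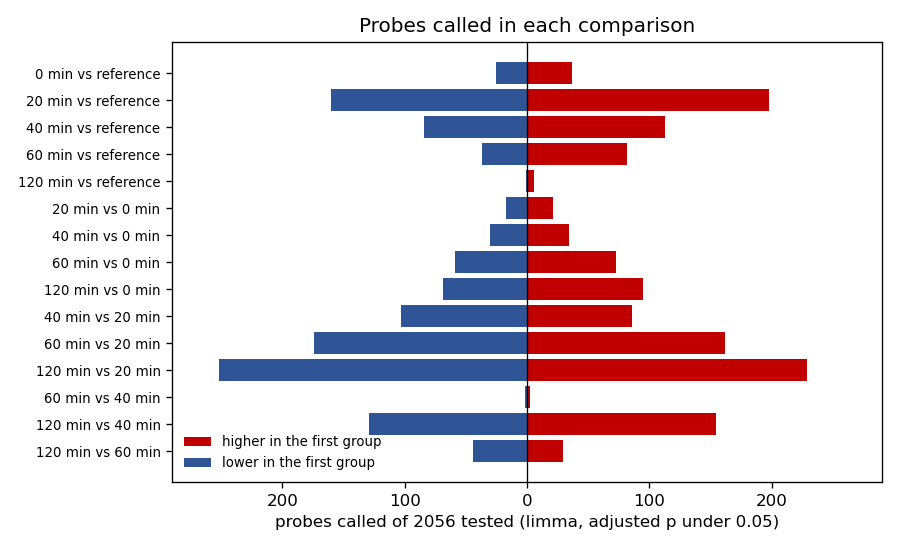
Number of probes called higher (right) and lower (left) in the first group named, of 2056 tested with limma at an adjusted p under 0.05, for each comparison on the vertical axis. The bars reach 229 higher and 252 lower probes for 120 against 20 min, and 6 higher and 1 lower for 120 min against the reference.

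Log ratios changed between 40 and 120 min at 90 °C. At 120 min 154 of 2056 probes were higher than at 40 min and 129 were lower (n = 4 each, limma, adjusted p under 0.05), with a median size of 0.29 log units. Against 60 min, 29 probes were higher at 120 min and 44 were lower. Between 40 and 60 min 4 probes were called, with 250 at an unadjusted p under 0.05. The 154 probes lower at 40 min had a median log ratio of -0.18 at 40 min, -0.057 at 60 min and 0.11 at 120 min, against 0.036 on the reference arrays. The 129 probes higher at 40 min had medians of 0.26, 0.13 and -0.032 at those times, against -0.0084 on the reference arrays. The group mean at 60 min lay between those at 40 and 120 min for 141 of the 154 probes and for 115 of the 129, against 49.8% and 48.6% of all tested probes lower and higher at 40 min. Choosing probes for a large gap between the outer times itself raises that share. The 120 min mean lay closer to the reference than the 40 min mean did for 67.5% of the 154 probes and 82.2% of the 129, beside 63.3% and 64.4% of all tested probes lower and higher at 40 min. The choice of probes bears on these shares and on the medians as well. The arrays of these 3 times and of the reference had few values at the spots that were measured mainly on the 0 and 20 min arrays. Fitted without the 0 and 20 min arrays, a check chosen after seeing the data, 303 probes were called between 40 and 120 min, 83 between 60 and 120 min and 3 between 40 and 60 min. The 120 against 40 min count was 185 without 40 min replicate 4 and 179 without 120 min replicate 3. The 120 against 60 min count was 45, 22 and 44 without 60 min replicates 1, 2 and 4, and 42, 30 and 34 without 120 min replicates 1, 2 and 3. With the arrays scaled to an equal spread, 46 probes were higher and 45 lower at 120 than at 60 min. This count was 142 (56 higher and 86 lower) with the slide-position trend removed, 174 (80 higher and 94 lower) with the 2 groups fitted alone and 121 with both spots kept. The 4 calls between 40 and 60 min became 0 without 40 min replicates 1 or 4 or 60 min replicates 1, 3 or 4, 1 without 40 min replicate 2, 2 without 60 min replicate 2 and 12 without 40 min replicate 3.

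Log ratios at 20 min differed from those at the later times. Against 20 min, 86 probes were higher and 103 lower at 40 min, 162 were higher and 174 lower at 60 min, and 229 were higher and 252 lower at 120 min (n = 4 each, limma, adjusted p under 0.05). Across probes, which are not independent replicates, the mean correlation between 20 min arrays and those of another time was 0.46 for 40 min, 0.39 for 60 min and 0.15 for 120 min, beside 0.65 among the 20 min arrays themselves. The ranges overlapped, from 0.310 to 0.620 for pairs of a 20 and a 40 min array and from 0.559 to 0.827 for pairs within 20 min. These comparisons also cross the difference in which spots hold a value, which cannot be told apart from time here. Without 40 min replicate 4 the 40 against 20 min count was 124. With the 2 groups fitted alone that count was 76 (36 higher and 40 lower). The 20 min replicates 1 and 2 correlated at 0.827 and replicates 3 and 4 at 0.686, beside 0.559 to 0.649 across these pairs. At 40 min, replicates 1 and 4 correlated at 0.664 and replicates 2 and 3 at 0.642, beside 0.457 to 0.571 across. The limma tests treat the arrays of a group as independent, a block by replicate number does not follow these pairs, and their cause was not tested.

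Against the 0 min sample, 21 probes were higher and 17 lower at 20 min, 34 were higher and 30 lower at 40 min, 73 were higher and 59 lower at 60 min, and 95 were higher and 69 lower at 120 min (n = 4 against 1, limma, adjusted p under 0.05). The median size of the called differences lay between 0.46 and 0.49 log units. With 1 sample at 0 min its own spread was not measured, so these calls assume that it varies like the other groups, and all but the 20 min comparison cross the difference in which spots hold a value. The 0 min sample had the highest correlation between neighbouring spots of the 19 arrays, at 0.546. Its 2 spots of a product correlated at 0.217, and at 0.686 with the slide-position trend removed. With the values as deposited, without centring, the balance turned, with 12 higher and 21 lower at 20 min, 26 and 42 at 40 min, 54 and 69 at 60 min, and 77 and 97 at 120 min. With the arrays scaled, 17 were higher and 6 lower at 40 min, and the counts at 20 and 60 min were 12 and 75. With the slide-position trend removed the counts were 11, 26 and 84 at 20, 40 and 60 min. Of the calls of the 4 comparisons, 23.7% to 53.0% were made again in the same direction. Fitting 2 groups alone gave 3, 12 and 318 at 20, 40 and 120 min. The counts were 22 without 20 min replicate 4, 77 without 60 min replicate 2, and 106 and 109 without 120 min replicates 1 and 2. With the replicate number as a block, the counts of all 4 comparisons fell by more than 1.5 times. Over all 5 irradiated times, 575 of 2056 probes (28.0%) differed between any of them by the moderated F test, which crosses the difference in which spots hold a value as well.

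The probes spread less widely around 0 at 120 min than at the earlier times. The SD of the log ratios across probes was 0.217 ± 0.022 at 20 min, 0.212 ± 0.027 at 40 min, 0.192 ± 0.013 at 60 min and 0.149 ± 0.012 at 120 min (mean ± SD, n = 4 each), beside 0.210 in the single 0 min sample and 0.130 ± 0.0062 on the reference arrays (n = 2). Each of the 20, 40 and 60 min arrays had a wider spread than each 120 min array, with a two-sided exact permutation p of 0.0286 for each of these comparisons, the smallest that 4 against 4 arrays allow. After adjustment over 6 comparisons the exact p was 0.0571, which did not pass the threshold. Leaving out 120 min replicate 1, 2, 3 or 4 gave a difference between 40 and 120 min of 0.0602, 0.0610, 0.0651 or 0.0689, each with an unadjusted exact p of 0.0571. Against the 2 reference arrays no group of 4 could give a p below 0.0667.

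**Figure D2:**
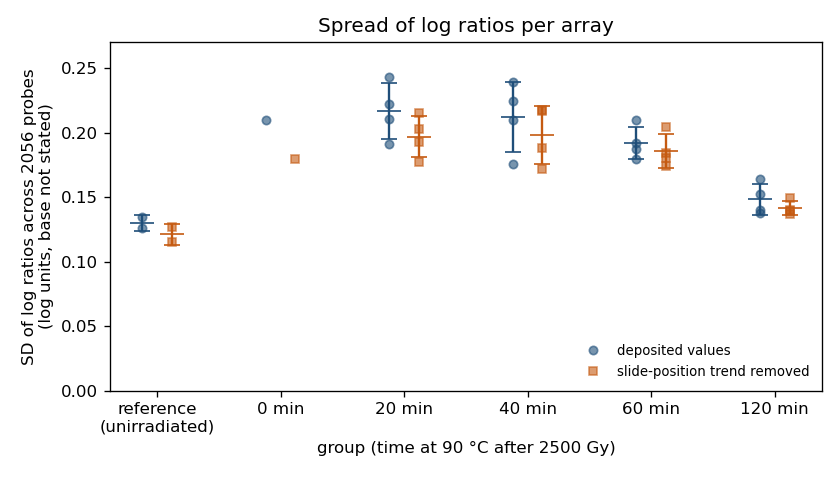
SD of the log ratios across the 2056 probes on each array (vertical axis, log units of unstated base) by group, for deposited values (circles) and after removal of the slide-position trend (squares), with bars for the mean ± SD. The 120 min arrays lie between 0.138 and 0.164 as deposited, below the lowest 40 min array at 0.176.

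Among probes called at 40 min whose values did not overlap those of the reference arrays, ID-3874 and ID-3228 were furthest above the reference and ID-2625 and ID-4093 furthest below it. ID-3874, in row 18 and column 10 of block 7, was 1.09 ± 0.21 log units (difference ± SE) above the reference at 40 min (limma adjusted p = 0.0023), 1.36 ± 0.29 above it in the single 0 min sample (adjusted p = 0.0149, with the spread taken from the other groups) and 0.068 ± 0.21 above it at 120 min (adjusted p = 0.949). ID-3228, in row 15 and column 12 of block 6, was 1.08 ± 0.13 above the reference at 40 min (adjusted p = 1.86e-05), 0.93 ± 0.13 at 60 min (adjusted p = 0.00011) and 0.59 ± 0.13 at 120 min (adjusted p = 0.0379). ID-4093, in row 3 and column 13 of block 8, fell by 0.65 ± 0.13 at 20 min (adjusted p = 0.0017) and by 0.62 ± 0.13 at 40 min (adjusted p = 0.0035), while the difference was 0.091 ± 0.13 at 120 min (adjusted p = 0.858). ID-2625, in row 14 and column 9 of block 5, fell by 0.74 ± 0.16 at 40 min (adjusted p = 0.004), but the reference arrays differed widely (mean 0.42 ± 0.75 SD, n = 2). Without reference replicate 2 its difference at 40 min was -0.21 and was not called. The call for ID-4093 was lost as well, at -0.58. The ID-2625 call was also lost when only the 40 min and reference arrays were fitted, with the difference unchanged at -0.74.

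**Figure D3:**
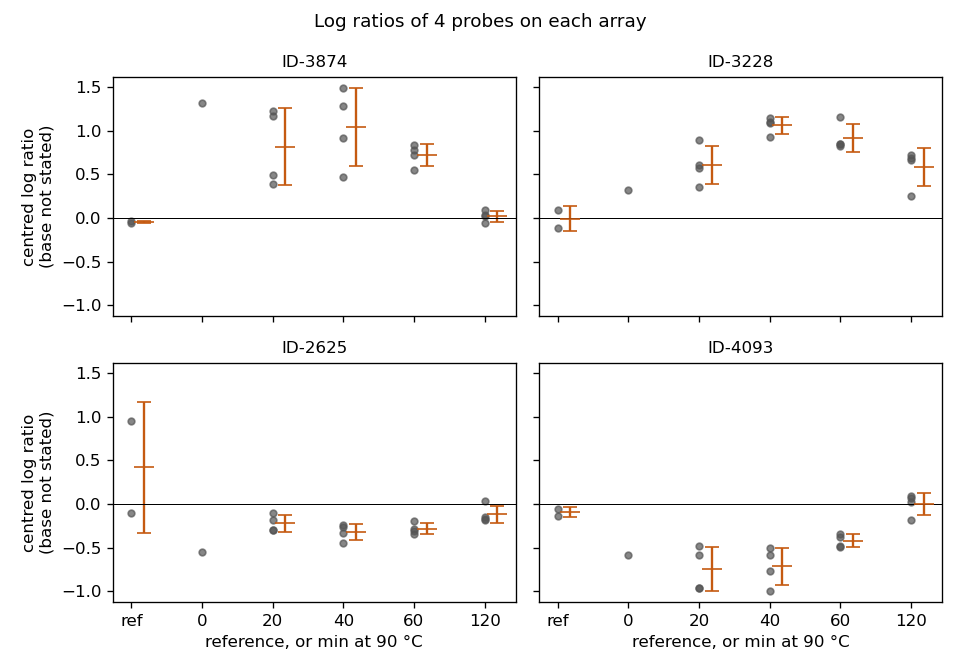
Log ratios of 4 probes on each array (points, vertical axis, base not stated), by group on the horizontal axis, with bars for the mean ± SD. ID-3874 has a mean of 1.04 at 40 min and 0.023 at 120 min, and ID-4093 a mean of -0.72 at 40 min and -0.00069 at 120 min.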

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

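The tests of slide position, of noise between spots, of a separate set of arrays and of the other splits of the arrays were chosen after the results were seen, as were the comparison of spreads itself and its recomputation over products with a value on all arrays. For that recomputation, and for noise at the seldom-measured spots, the outcome each explanation would give was written down before the value was computed, but after the pattern had been seen.

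The 0 and 20 min arrays held 4432 values at 1226 spots that had a value on at most 6 of the 19 arrays, where the other 14 arrays held 44, and 97.2% of these spots lay in rows 7, 8, 19 and 20 of their blocks. All but 4 of these values, at 2 spots, belonged to probes that were not tested. Values of untested probes still entered the array medians used for centring and the neighbour means of the position trend. Noise of single spots would give a correlation between the 2 spots of a product under 0.1, and the lowest of the 5 arrays gave 0.3083 with the position trend removed. That cleared the bound of 0.3 set beforehand by less than its error. The case against such noise therefore rests on the 95% lower bound of that correlation, 0.224, compared with 0.1 only after the value was seen. The bound treats the spot pairs as independent, although neighbouring spots were correlated, so it may lie too high. Whether another print of the slides or another filter by the authors left these values stays open, and no biological explanation was tested.

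The 20 min arrays differed from the 40, 60 and 120 min arrays, and this difference runs along the boundary in which spots hold a value. The 40 against 20 min comparison called 189 probes where 60 against 40 min, which does not cross that boundary, called 4. Another set of arrays or another processing at 0 and 20 min and an early change with time would both give this, so they cannot be told apart. A slide-position trend as the whole cause would leave under 10% of the 481 calls of 120 against 20 min once the trend was removed. Of these calls, 54.05% were made again in the same direction (95% Wilson interval 49.6% to 58.5%). The interval treats probes as independent, which they are not, so it does not give the error of the share over arrays. The share argues against the removed trend as the whole cause, while any trend the smoothing left behind was not tested. Time after irradiation and time since rewarming remain open as biological explanations, with no chilled and unirradiated group among these samples.

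The spread of log ratios was narrower at 120 than at 40 min, though the exact p of 0.0286 became 0.0571 after adjustment over 6 comparisons. The difference was 0.05689 after the slide-position trend was removed, 0.06099 for the spread that both spots of a product share with the trend removed, and 0.06656 over products with a value on all arrays, and in each case all 4 arrays at 40 min lay above all 4 at 120 min. These values argue against the position trend that was removed, spot noise and missing values as the cause. The authors' normalisation and a hybridisation batch that follows the time point were not tested and stay open, so a return of expression toward the unirradiated state is only a hypothesis here.

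Taken one at a time, chance is excluded at a share under 0.05 for 5 of the 6 comparisons between the 4-array groups, each counted over 35 splits of its 8 arrays. A share of 1 in 35 is the smallest possible, it was not adjusted over the 6 comparisons, and these were chosen after their counts had been seen. The real split alone (1 of 35) gave as many calls for 40 against 20 min (189, highest other 55), 60 against 20 min (336, highest other 0), 120 against 20 min (481, highest other 0), 120 against 40 min (283, highest other 8) and 120 against 60 min (73, highest other 0). For 60 against 40 min, 2 of 35 splits gave at least the real 4 calls and the highest other gave 24, so chance cannot be excluded there. That split set 60 min replicates 1 and 2 with 40 min replicates 2 and 3 against the rest, and the 55-call split of the 20 and 40 min arrays parted the 40 min replicates in the same way. The deviations of 40 and 60 min arrays from their group means correlated above 0 for 7 of 8 pairs within a side of the 24-call split (-0.031 to 0.316) and below 0 for 7 of 8 pairs across it (-0.252 to 0.021), values of the same arrays that gave the split and so no independent test of a structure other than time.

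Among 40 groups of 4 values tested for a single distant sample, 5 were marked, where chance marks about 1 in 20 of independent groups. These groups were not independent, so an excess over chance cannot be read from the count. The spot correlation of 1 array was marked with and without the trend, and the 4 named probes were picked for large differences. The correlation between the 2 spots of a product on 120 min replicate 4 was 0.2858, beside 0.572 to 0.623 on the other 120 min arrays, and 0.3908 beside 0.639 to 0.684 with the position trend removed. The reference arrays and the 0 min sample were too few for this test. Reference replicate 2 had a lower correlation still, 0.198, and 0.247 with the trend removed. Probe ID-3228 had a log ratio of 1.164 on 60 min replicate 2, beside 0.825 to 0.854, and of 0.2583 on 120 min replicate 4, beside 0.669 to 0.720. Probe ID-2625 had a log ratio of 0.03237 on 120 min replicate 2, beside -0.183 to -0.147.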

How the results depend on the processing

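The slide-position correction and all alternatives for the comparisons among 20, 40, 60 and 120 min and for the spread were chosen after seeing the data. Of 245 recomputed counts of calls, 173 stayed within 1.5 times the reported count and 72 did not; the count over the irradiated times stayed within it in all 24 alternatives (471 to 607). For the changes below the cause was not tested, except that fits of fewer arrays have fewer degrees of freedom. Scaled arrays gave 196 (60 min) and 90 (120 min) calls against the reference, 12, 23 and 75 for 20, 40 and 60 min against 0 min, and 0 for 60 against 40 min. With the position trend removed the counts were 28, 179 and 12 for 0, 60 and 120 min against the reference, 11, 26 and 84 for 20, 40 and 60 min against 0 min, 2 for 60 against 40 min and 142 for 120 against 60 min. Both spots kept gave 112 and 11 for 0 and 120 min against the reference, 15 for 60 against 40 min and 121 for 120 against 60 min. Fitting 2 groups alone gave 123, 75 and 14 for 0, 40 and 120 min against the reference, 3, 12 and 318 for 20, 40 and 120 min against 0 min, 76 for 40 against 20 min, 0 for 60 against 40 min and 174 for 120 against 60 min. The ratio against 0 gave 174, 795, 682, 666 and 334 at 0, 20, 40, 60 and 120 min. It leaves out the mean of the reference arrays and its error, but those arrays stay in the shared spread. Any dye bias of single probes stays in this ratio, so its larger counts cannot be read as expression alone. Same-number arrays did not deviate alike on average (mean correlation of deviations -0.031 over 24 same-number pairs, 0.010 over 72 others). The 2 means are not independent, since deviations from a group mean sum to 0 within the group. With the replicate number as a block, 16, 35, 61 and 72 probes were called for 20, 40, 60 and 120 min against 0 min. No other count moved past 1.5 times with this block.

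Leaving out each array in turn gave 14 to 53 calls at 0 min, 131 to 357 at 20 min, 51 to 256 at 40 min, 31 to 110 at 60 min and 1 to 28 at 120 min against the reference; 22 to 41, 59 to 81, 77 to 109 and 106 to 131 at 20, 40, 60 and 120 min against 0 min; 124 to 201 for 40 against 20 min, 244 to 296 for 60 against 20 min, 336 to 455 for 120 against 20 min, 0 to 12 for 60 against 40 min, 179 to 318 for 120 against 40 min and 22 to 72 for 120 against 60 min. The spread difference ranged from 0.05487 to 0.07597 between 40 and 120 min, 0.03791 to 0.04878 between 60 and 120 min, 0.05954 to 0.07687 between 20 and 120 min and 0.01119 to 0.03229 between 40 and 60 min. Leaving out the single 0 min sample gives no value. Of 64 recomputed values for the 4 named probes at 40 min against the reference, 61 kept their direction and call. Their values at the other times were not recomputed. These probes were picked as the largest called differences of this same comparison, and some alternatives, such as robust moderation, leave the difference itself unchanged. The share kept is therefore no independent support for the calls. The alternatives for the 23 gene lists were not run, and signal over background was not analysed here.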

Other observations

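The comparisons of single pairs of arrays were made after the data were seen. Across probes, which are not independent replicates, 40 min replicate 3 correlated at 0.738 with 60 min replicate 1, above each of the 6 pairs within the 40 min group, the highest of which was 0.664. The mean correlation between 40 and 60 min arrays was 0.593 over 16 pairs, beside 0.574 over the 6 pairs within 40 min. The 0 min sample correlated with the other groups at a mean of 0.461 for 20 min, 0.395 for 40 min, 0.338 for 60 min and 0.122 for 120 min, and the reference arrays at -0.0036 for 20 min, 0.0854 for 40 min, 0.171 for 60 min and 0.231 for 120 min. The 2 reference arrays correlated at 0.262 with each other. They carried unirradiated RNA in both channels, so a correlation with them does not measure closeness to the unirradiated state.

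Neighbouring spots had correlated log ratios on each of the 19 arrays, from 0.130 to 0.546. The 2 spots of a product correlated at 0.198 to 0.777, and at 0.247 to 0.821 once the position trend was removed. Reference replicate 2 was lowest both before and after that removal, and also had the fewest spots with a value (3556). The deviations of the 2 spots from their group means had a consensus correlation of -0.063 before that removal. Removing the trend also changed which probes were called: of the 283 probes called between 120 and 40 min, 183 were called in the same direction among the 299 called after removal, and of the 197 called at 40 min against the reference, 111 were called in the same direction among 174. For the comparisons with the single 0 min sample, the probes called in the same direction after removal were 9 of 38 (23.7%) for 20 min, 25 of 64 (39.1%) for 40 min, 64 of 132 (48.5%) for 60 min, 87 of 164 (53.0%) for 120 min and 19 of 62 (30.6%) for the reference. Called probes whose difference changed sign after removal, called again or not, numbered 4 for 20 min against the reference. They numbered 1 each for 0 min against the reference, 60 against 0 min and 120 against 20 min, and 0 in the other comparisons.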
